A study of Homo sapiens with 8 samples.

How the data were processed

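Gene expression was measured with 1-colour Agilent whole human genome arrays in 4 human cell types, each on 2 arrays. The cell types were H1 embryonic stem cells, IMR90 fetal lung fibroblasts, keratinocytes held for 48 hours in 1.5 mM calcium chloride, and primary hepatocytes. The labels call the arrays of each type biological replicates 1 and 2. Per the labels, total RNA was extracted with Trizol and an RNeasy kit, copied into random-primed cDNA and labelled with Cy3. The file headers place the 4 H1 and IMR90 arrays on slide 1 and the 4 keratinocyte and hepatocyte arrays on slide 2, with a different scan number for each slide. Slide and cell type therefore cannot be told apart in the 4 comparisons between slides.

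The deposited scanner files hold intensity per spot, per the file headers, written by Agilent Feature Extraction 9.5.3.1. The signal used was the processed signal, from which the scanner software had subtracted background and a spatial trend on each array, with no scaling between arrays. The same files hold the raw mean intensity of each spot and the median intensity of its local background, per the file headers. A deposited table of values per array also holds intensity; it ranks the spots as the scanner signal does, but the ratio between the values varies with brightness and its normalization is not stated. Its columns have a maximum of 81416.76 on all arrays but hepatocyte replicate 1. Array coordinates refer to genome build hg17 and are given as in the files. No per-sample column was left unread.

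Each array had 45015 spots, of which 1639 were control spots and 43376 carried 41000 distinct probes. Of these, 104 probes for X-inactivation and Y-linked genes were left out of every step. Gene symbols were updated for 23371 probes through their accession and for 1037 through an older symbol of a single gene, and 16488 probes kept the name in the file. Spots flagged as outliers by the scanner software were left out, and repeated spots of a probe were averaged. The log2 processed signal minus the array's 75th percentile over non-control probes is called the level here. A gene was represented by a single probe, a choice that mattered for 7499 genes with several probes. Probes with a usable value in every cell type came first, and among those the highest mean over the 8 arrays decided. The background filter below was applied to the chosen probe. Probes were kept if well above background, in the scanner software's own test, on both arrays of at least 1 cell type. This left 25826 of 30901 genes, 25807 of them tested in at least 1 comparison and 20986 with a value on all 8 arrays.

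The share of probe spots well above background was 69.16% and 70.55% on H1 replicates 1 and 2, and 66.93% and 64.76% on IMR90 replicates 1 and 2. It was 78.96% and 79.51% on the keratinocyte arrays and 80.92% and 76.24% on the hepatocyte arrays. The 75th percentile of the intensity was 1322 and 1357 in H1, 1540 and 1506 in IMR90, 1708 and 1757 in keratinocytes, and 838 and 826.1 in hepatocytes. Saturated spots numbered 1974 and 1873 in H1, 2471 and 2336 in IMR90, 708 and 731 in keratinocytes, and 408 and 405 in hepatocytes. Spots flagged as non-uniform numbered 4464 and 3964 in H1 and 3234 and 4735 in IMR90, against 114 and 116 in keratinocytes and 40 and 43 in hepatocytes. With 2 arrays per cell type, the number of arrays limits the precision of every value.

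All 8 arrays entered a single limma fit (lmFit and eBayes, limma 3.58.1) with a coefficient per cell type and no block, so that the 4 groups shared an estimate of the spread, with 1.26 prior degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p within a comparison was below 0.05 and its absolute log2 difference at least 1. Of the 6 comparisons, H1 minus IMR90 and keratinocytes minus hepatocytes lie within a slide. A fold is called "at least" when a side was well above background on neither array or was saturated. A dim side was then set to the lowest level well above background on its arrays, and a saturated side was left at its recorded level. By a rule added after the results were seen, a dimmer side well above background on 1 of its 2 arrays also gives a fold of "at least", with the dim array raised in the same way, and so does a brighter side saturated on 1 array. No fold is given when both sides were dim or both saturated.

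The 27 gene lists, the rule for named genes and all settings below but those stated otherwise were chosen before the data were examined. The lists covered pluripotency, fibroblast matrix, lung mesenchyme regulators, contractile and mesenchymal genes, keratinocyte differentiation, basal keratinocyte genes, epithelial junctions, plasma proteins, drug and bile acid metabolism, urea cycle with amino acid and glucose metabolism, and liver transcription factors. The others were the HOXA, HOXB, HOXC and HOXD clusters, Polycomb, CTCF and cohesin, DNA methylation, mitosis and DNA replication, interferon response, immediate early and stress genes, housekeeping genes, and markers of leukocytes, endothelium, bile ducts, melanocytes and early lineages. Each list was tested with camera at a preset inter-gene correlation of 0.01, on its members with a value on all 8 arrays, with adjustment over the 27 lists of a comparison, and again with an estimated correlation. With an estimated correlation, camera judges a list on the few residual degrees of freedom of the 8 arrays. At the preset correlation it uses the number of genes instead. The p with an estimated correlation is thus higher even where that correlation is below the preset one. Member calls were adjusted over all genes tested and adjusted over the list alone.

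The genes named follow a fixed rule. In the 2 comparisons within a slide, these were the 5 called genes with the largest log2 difference in each direction, among genes measured and unsaturated on all 4 arrays whose arrays did not overlap. From each described list the first 4 tested members were named. For each cell type the rule took the 3 genes, well above background and unsaturated on all 8 arrays and highest in that type, with the largest smallest difference from the others. Every one of the 11 HOXA genes was also covered. Other members named as exceptions to a count were chosen after their values were seen.

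The fit was tested on simulated data with 50 changed genes per size. For H1 minus IMR90, 0% of changes of 0.5 log2, 16% of 1, 64% of 2 and 70% of 4 were recovered, with untested genes counted as missed. For keratinocytes minus hepatocytes the shares were 0%, 30%, 76% and 82%. Of the unchanged genes, 6 of 23547 and 6 of 25588 were called. A change of 0.5 log2 lies below the fold threshold, which largely set the 0%, and a change of 1 lies at it. Few genes were changed in the simulation, while 16367 of 23807 passed the adjusted p in the real H1 minus IMR90 fit. The adjustment was thus stricter in the simulation, so neither these shares nor the calls of unchanged genes describe the real calls. A list of 25 genes shifted by 1 log2 gave a camera p of 1.73e-46 in H1 minus IMR90. A random list of 25 genes gave a p of 0.404 there and 0.753 in keratinocytes minus hepatocytes, but 0.00176 in IMR90 minus hepatocytes.

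The alternatives written in advance were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization alone, median centring, the deposited table, no filter on dim probes, a filter on all 8 arrays, and the mean of a gene's probes. They further included a trended robust variance, a replicate block, a fit on the 4 arrays compared (the same arrays as a slide alone for comparisons within a slide), the adjusted p alone, an absolute log2 difference of at least 2, the estimated correlation, and leaving out each array in turn. Added after seeing the data were keeping outlier spots, mapping signals on 5 of the 10 E1A spike-ins, averaging the keratinocyte and the hepatocyte arrays to 1 sample each, a crossed replicate block, and leaving out calls with both sides dim or saturated. Tools were R 4.3.3 with version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the figures.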

Results

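The data were 8 single-colour expression arrays from 4 human cell types with 2 arrays each. H1 is an embryonic stem cell line and IMR90 a line of fetal lung fibroblasts. Keratinocytes, the main cells of the epidermis, had been held for 48 hours in 1.5 mM calcium chloride, which makes them stratify and mature in culture. The hepatocytes were primary liver cells. The series describes an expression profile of these types and states no further question, so each comparison asks which genes differed between a pair of types. Between 64.76% and 80.92% of probe spots per array were well above background. Levels are log2 intensities relative to an array's 75th percentile, and errors are the standard error (SE) of a log2 difference or the SD of 2 arrays.

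The arrays of a type differed by a median of 0.115 log2 in H1, 0.174 in IMR90, 0.0395 in keratinocytes and 0.0487 in hepatocytes. Among probes printed on 10 spots of each array, 7.08% in keratinocytes and 7.2% in hepatocytes differed between the arrays of a type by over 2 SE of the spot noise. The share was 18.1% in H1 and 59.9% in IMR90. The keratinocyte and hepatocyte pairs thus differed by about as much as repeated spots of an array did. If the arrays of such a pair held 1 RNA sample, n would be 1 per type and the p values of keratinocytes minus hepatocytes would describe array noise. With those pairs averaged to 1 sample each, so that the spread comes from the H1 and IMR90 arrays alone, keratinocytes minus hepatocytes gave 8638 called genes in place of 10322, and H1 minus IMR90 gave 9716 in place of 10305. In that setting NANOG was called in none of the 3 comparisons with H1, with its differences unchanged (log2 7.37, adjusted p = 0.0799 in H1 minus IMR90), and in keratinocytes minus hepatocytes EPCAM, OAS1, CDH5 and HOXB5 were no longer called.

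Control RNAs of a known mix, the E1A spike-ins, had been added to the samples. Between the dimmest and the brightest of the 5 spike-ins used, signals spanned 10.58 to 11.34 log2 on the slide 1 arrays and 7.99 to 8.08 on the slide 2 arrays.

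**Figure D1:**
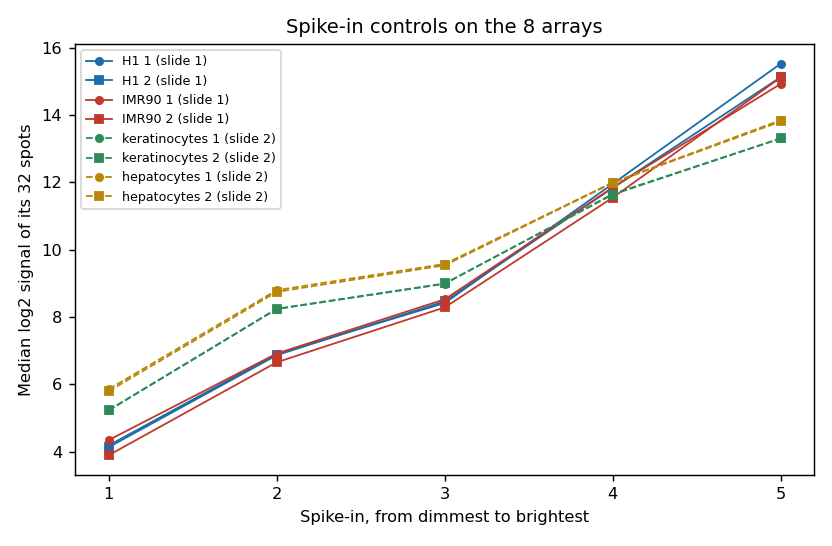
Log2 signal of the 5 unsaturated spike-ins on each of the 8 arrays, by slide. The dimmest spike-in had a mean of 4.15 on slide 1 and 5.53 on slide 2, and the brightest 15.18 and 13.57.

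H1 cells and IMR90 fibroblasts were compared on slide 1. Most tested members of the pluripotency and epithelial junction lists were higher in H1, and most of the fibroblast matrix, contractile and mesenchymal, lung mesenchyme and HOXB lists were higher in IMR90. These lists passed camera at the preset correlation and none did with an estimated one (lowest adjusted p = 0.0659 with an estimated correlation). A high correlation need not be the reason for every list, since the estimated test rests on few residual degrees of freedom. For the pluripotency list the estimated correlation was 0.428 and the camera p rose from 8.97e-04 to 0.229, so a high correlation can add to the rise there. For the fibroblast matrix list the estimated correlation was -0.017, below the preset 0.01, yet the camera p rose from 3.86e-10 to 0.00244. SOX2, a transcription factor needed for pluripotency, was at least 1600-fold higher in H1 (log2 11.44 ± 1.40 SE, n = 2 arrays per type, limma adjusted p = 8.69e-04). FMOD, which encodes the collagen-binding proteoglycan fibromodulin, was 1080-fold higher in IMR90 (log2 -10.08 ± 0.08, adjusted p = 1.55e-07). Of 23807 genes tested, 10305 were called, 5828 higher in H1 and 4477 higher in IMR90. The share higher in H1 was 56.6%, and 50.6% with median centring and 49.4% with the deposited table. For 3102 of these a side was not above background, and for 437 neither was.

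Besides SOX2, the pluripotency genes higher in H1 included NANOG, another core factor of the stem cell state, which was at least 165-fold higher (log2 7.37 ± 1.64, adjusted p = 0.0159, 1 usable H1 array). DNMT3B, a DNA methyltransferase active in early embryos, was at least 102-fold higher (log2 6.68 ± 0.65) and rested on 1 usable IMR90 array. In all, 15 of 17 tested members were higher in H1 and none in IMR90, with a median log2 difference of 8.70. The list passed camera (adjusted p = 0.00484), but not with an estimated correlation (adjusted p = 0.515 with an estimated correlation) or with the deposited table (0.176). POU5F1, the third core factor, was saturated in H1 and missed the threshold (log2 5.93 ± 2.36, adjusted p = 0.0713), as did FOXD3. POU5F1 passed it with quantile normalization and with the deposited table (adjusted p = 0.0423 in each).

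On IMR90 replicate 1, POU5F1 had a level of 3.62 against -4.03 on replicate 2. SOX2 was at -3.61 against -8.14, NANOG at -2.53 against -6.29 and L1TD1, an RNA-binding protein of stem cells, at -1.17 against -8.11. L1TD1 was chosen after its values were seen. Without IMR90 replicate 1, the H1 minus IMR90 difference was 9.76 for POU5F1 (adjusted p = 2.5e-06; 2.11 without replicate 2 instead, adjusted p = 4.43e-05), 13.71 for SOX2 and 9.25 for NANOG, and 16 of 17 members were higher in H1. Without this array, 9966 genes were called in H1 minus IMR90.

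**Figure D2:**
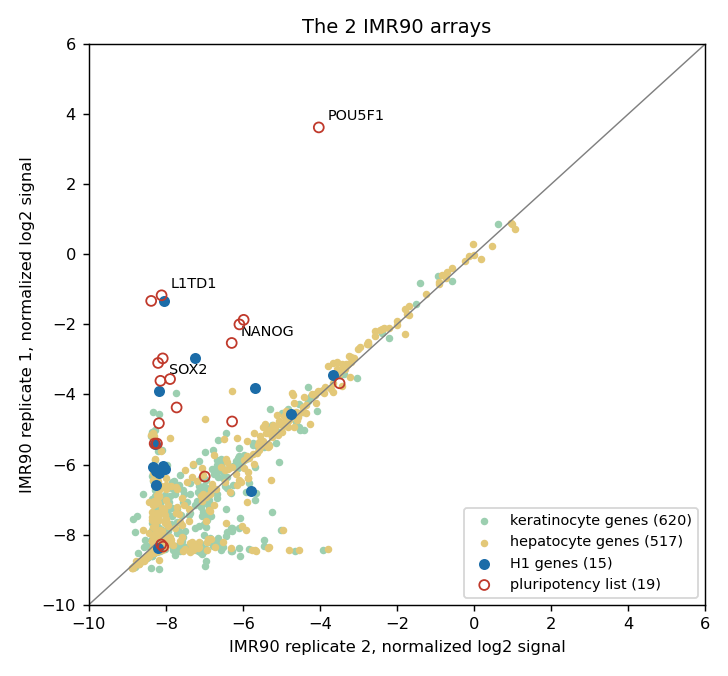
Each point is a gene, with its level on IMR90 replicate 2 on the horizontal axis and on IMR90 replicate 1 on the vertical axis, both in log2 relative to the array's 75th percentile. Genes measured in H1 but dim in keratinocytes and hepatocytes lie above the diagonal by a median of 1.95 (n = 15), while keratinocyte genes (n = 620) and hepatocyte genes (n = 517) lie near it.

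Other genes with the largest measured differences toward H1 were TNFRSF8, which encodes the CD30 receptor, and RGMA, a guidance molecule of the nervous system. TNFRSF8 was 626-fold higher (log2 9.29 ± 0.47, adjusted p = 2.46e-05; probe on chromosome 1, 12138427 to 12138486) and RGMA 587-fold higher. COL9A3, a cartilage collagen chain, was 310-fold higher, the noncoding RNA MIAT 296-fold and B3GAT1, which makes a carbohydrate epitope of neural cells, 197-fold. TNFRSF8 and RGMA also differed between the IMR90 arrays, with SDs of 0.95 and 0.98. Without IMR90 replicate 1 their differences were 9.96 and 9.89.

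The genes of epithelial junctions were higher in H1 for 15 of 20 tested members and lower for 1, PKP1, a plaque protein of desmosomes. CDH1, the adhesion molecule E-cadherin, was at least 475-fold higher in H1 (log2 9.42 ± 1.70, adjusted p = 0.00441) and the epithelial adhesion molecule EPCAM at least 569-fold higher. ESRP1, a splicing regulator of epithelia, was 63.4-fold higher. The list's median was 5.12 (camera adjusted p = 7.18e-04, and adjusted p = 0.182 with an estimated correlation). CDH1 and EPCAM also stood higher on IMR90 replicate 1, with IMR90 SDs of 3.59 and 2.15. Without that array their differences were 11.96 and 10.68.

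Fibroblast matrix genes were higher in IMR90 for 20 of 23 tested members and in H1 for none, with a median of -6.51 (camera adjusted p = 1.04e-08, and adjusted p = 0.0659 with an estimated correlation). The fibrillar collagen genes COL1A1 and COL1A2 were saturated in IMR90, at least 22.9-fold and at least 3.22-fold higher there. COL3A1 differed at least 1530-fold on the 1 usable IMR90 array, where 1 of 2 arrays was saturated, and fibronectin (FN1) at least 6.97-fold. COL5A1, a minor fibrillar collagen, was 315-fold higher and PDGFRA, a growth factor receptor of mesenchymal cells, 390-fold (log2 -8.61 ± 0.05, adjusted p = 1.29e-07). NFIX, a transcription factor, was 935-fold higher in IMR90 and LRRC17, a secreted leucine-rich repeat protein, 499-fold.

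All 8 tested lung mesenchyme regulators were higher in IMR90 (median -8.30, camera adjusted p = 3.52e-05, and adjusted p = 0.153 with an estimated correlation). The forkhead factor FOXF1 was at least 5540-fold higher and the T-box factors TBX2 and TBX5 at least 4860-fold and at least 44.4-fold. FOXF2 was at least 166-fold higher on 1 usable IMR90 array. These 4 genes were not above background in H1 on the probes used. Contractile and mesenchymal genes were higher in IMR90 for 11 of 16 (median -4.14, camera adjusted p = 0.00687, and adjusted p = 0.179 with an estimated correlation). Among them smooth muscle actin (ACTA2) differed at least 9.18-fold, the actin-binding protein transgelin (TAGLN) at least 2.38-fold (log2 -1.25, or -0.93 and not called without H1 replicate 2), and TWIST1, a regulator of mesenchymal identity, 13.6-fold (log2 -3.76 ± 0.20). Vimentin (VIM) was saturated on all 4 arrays and gives no fold.

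HOX genes set position along the body axis. In the HOXA cluster 5 of 9 tested genes were higher in IMR90 and none in H1, or 4 of 9 without the HOXA10 call, which rests on a chromosome 12 probe, with a median of -2.07, or -0.93 with dim sides at their bound (camera adjusted p = 0.00823, and adjusted p = 0.409 with an estimated correlation and 0.932 with the deposited table). HOXA5 was at least 166-fold higher in IMR90 (log2 -9.25 ± 0.09, adjusted p = 1.77e-07; chromosome 7, 26954787 to 26954846), HOXA4 at least 97.3-fold, HOXA2 at least 22.8-fold and HOXA9 at least 3.72-fold. HOXA6 and HOXA11 were not above background in either type. HOXA7 had no usable IMR90 array. The deposited table lacks values for many dim spots, so list tests on it leave out members that are dim in a type. HOXB genes were higher in IMR90 for 7 of 9 (median -6.41, camera adjusted p = 0.00193, and adjusted p = 0.176 with an estimated correlation and 0.307 with the deposited table), among them HOXB2 by at least 409-fold, HOXB3 by at least 529-fold, HOXB4 by at least 147-fold and HOXB5 by at least 306-fold. In the HOXC cluster, HOXC8 and HOXC9 of 7 were higher in IMR90, by at least 3.03-fold and at least 6.18-fold. HOXC6 and HOXC10 were not above background in either type (list median -0.31, camera adjusted p = 0.0942, or 0.0482 without either hepatocyte array and 0.0421 with the pairs averaged). None of 6 HOXD genes was called in H1 minus IMR90 (limma with eBayes; median 0.42, camera adjusted p = 0.81).

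The probes of 2 HOXA genes need care. HOXA3's brighter probe (chromosome 7, 26923159 to 26923218) was bright or saturated in every type, while its other probe (26920011 to 26920070) had a level of -8.5 in H1 and 0.12 in IMR90. HOXA10's brightest probe lies on chromosome 12 (52709820 to 52709879), next to the HOXC6 probe, and the HOXA10 calls rest on it. The 2 HOXA10 probes on chromosome 7 were above background on both arrays in keratinocytes and in no other type.

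**Figure D3:**
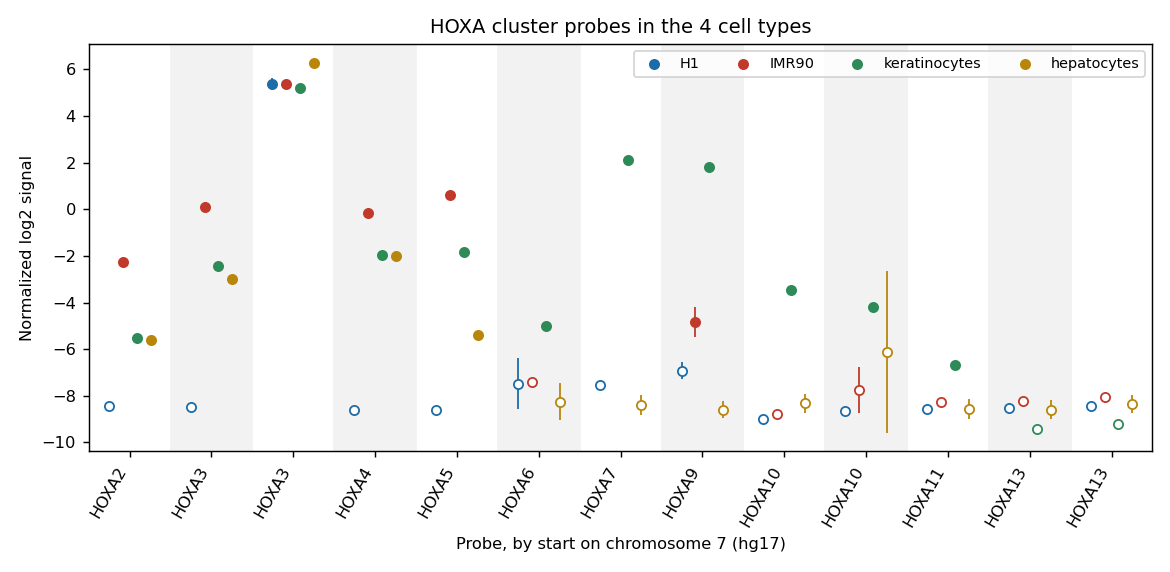
Mean level of HOXA probes in the 4 cell types, in log2 relative to the array's 75th percentile on the vertical axis, with probes in order along the cluster; bars are the SD of 2 arrays. HOXA5 stood at 0.62 in IMR90, -1.85 in keratinocytes, -5.38 in hepatocytes and -8.63 in H1.

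Genes of the immediate early and stress response, which react within minutes to growth factors and handling, were higher in IMR90 for 13 of 18 and in H1 for none (median -3.38, camera adjusted p = 0.00823, and adjusted p = 0.179 with an estimated correlation). JUN was saturated in IMR90 and at least 13-fold higher there, and EGR1, a growth-induced transcription factor, was 5.30-fold higher on 1 usable H1 array. FOS (log2 0.89) and ATF3 (log2 0.90) lay below the fold threshold, but ATF3 was at 1.00 and called as higher in H1 without H1 replicate 1. The list's adjusted p was 0.0521 without IMR90 replicate 2. Genes of mitosis and DNA replication were higher in H1 for 9 of 18 and in IMR90 for 1, the cell cycle transcription factor E2F1 (median 0.99, camera adjusted p = 0.0352, and adjusted p = 0.219 with an estimated correlation). BUB1, a spindle checkpoint kinase, was 5.71-fold higher in H1 and cyclin A2 (CCNA2) 2.63-fold. MKI67 (log2 0.82, adjusted p = 0.0257) and CDK1 (log2 -0.62, adjusted p = 0.337) were not called, but CDK1 was at -1.46 and called without H1 replicate 2. The list's adjusted p was 0.0966 without that array, 0.0735 with quantile normalization, 0.0994 with the deposited table and 0.198 with signals mapped on the spike-ins.

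Polycomb genes, whose products hold developmental genes silent, went both ways. JARID2, a cofactor of the methylating complex, was 33.7-fold higher in H1 (log2 5.07 ± 0.78, adjusted p = 0.00229), and PHC1 was the only other member of 26 higher there, while 9 were higher in IMR90 (median -0.23, camera adjusted p = 0.0181, and adjusted p = 0.307 with an estimated correlation; adjusted p = 0.0966 without H1 replicate 2, 0.102 with outlier spots kept, 0.0704 with the mean of probes and 0.0574 with the deposited table). The catalytic subunits EZH2 (log2 0.89, or 1.14 and called with outlier spots kept) and EZH1 (log2 -0.02) and the core subunit SUZ12 (log2 -0.09 on 1 usable array per type) were not called, and with the mean of its probes SUZ12 turned to 2.08 (adjusted p = 0.0223). Interferon response genes were higher in IMR90 for 7 of 16 and in H1 for 2, MX1 and BST2 (median -0.39, camera adjusted p = 0.152). The antiviral gene MX1 was 8.39-fold higher in H1. IFIT1 (log2 -0.34) and IFI27 (log2 0.15) were not called, and OAS1 was not above background in either type.

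**Figure D4:**
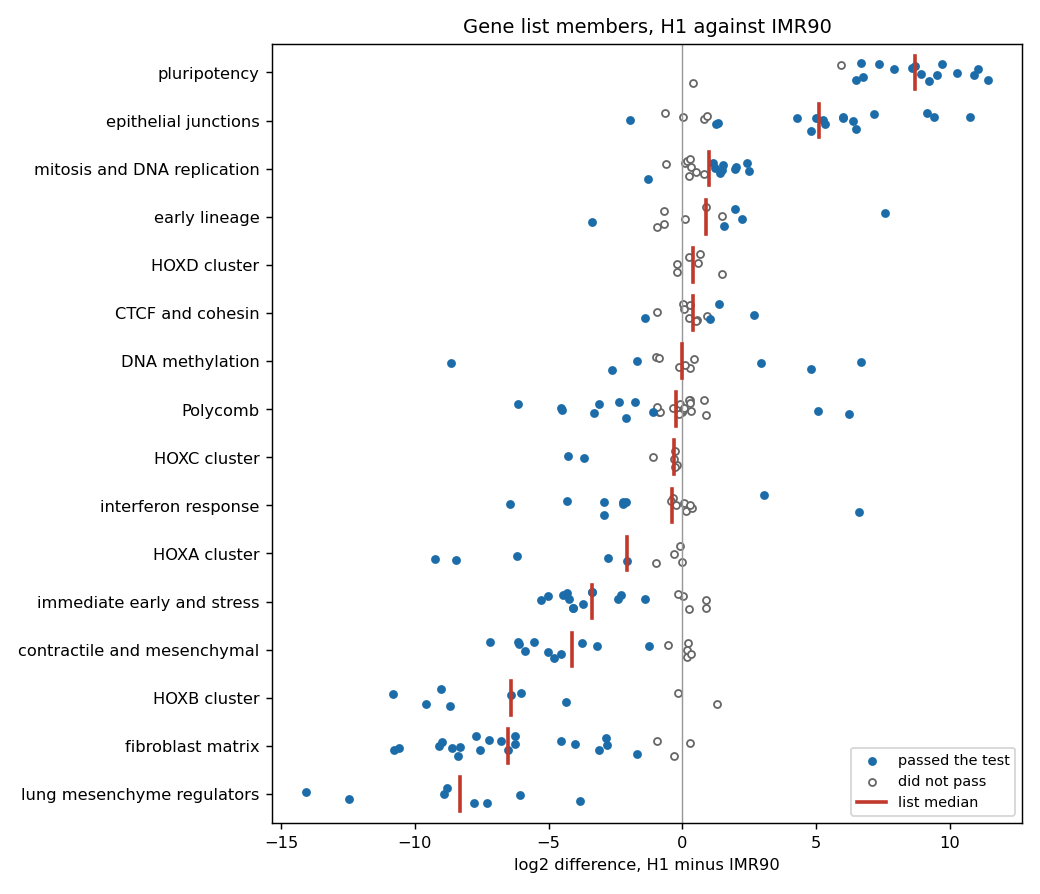
Log2 difference H1 minus IMR90 of each tested member of the gene lists on the horizontal axis, a row per list, with the list's median marked. Pluripotency members had a median of 8.70 and lung mesenchyme regulators a median of -8.30.

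Counts of members were the same when adjusted over the list alone, for every list described in this comparison and the others but housekeeping genes in keratinocytes minus hepatocytes. Of 27 lists, 10 passed camera in H1 minus IMR90, 1 with the filter on all 8 arrays and 0 with an estimated correlation. The number of called genes was 6710 with normexp and quantile, and HOXA9, HOXA10, PKP1 and DNMT3L were then below the fold threshold. Among 4312 genes with several measured probes, 56 had probes that differed in opposite directions (1.3%).

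Keratinocytes and hepatocytes were compared on slide 2. Most tested members of the keratinocyte differentiation, basal keratinocyte, epithelial junction and interferon response lists were higher in keratinocytes. Most of the plasma protein, drug and bile acid metabolism, urea cycle and glucose, and liver transcription factor lists were higher in hepatocytes, and so were most of the fibroblast matrix, contractile, leukocyte, endothelial and mitosis lists. These lists passed camera at the preset correlation and none did with an estimated one (lowest adjusted p = 0.0555 with an estimated correlation). LCE3D, a late cornified envelope protein, was 1600-fold higher in keratinocytes (log2 10.64 ± 0.10, n = 2 arrays per type, limma adjusted p = 2.43e-07). FGG, a chain of the clotting protein fibrinogen, was 5990-fold higher in hepatocytes (log2 -12.55 ± 0.13, adjusted p = 2.63e-07).

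Of 25791 genes tested, 10322 were called, 3968 higher in keratinocytes and 6354 higher in hepatocytes. For 1876 of these a side was not above background, for 148 neither was, and for 224 both sides were saturated, where the scaling alone sets the difference between the ceilings. The share of calls higher in keratinocytes was 38.4% and moved with the scaling, to 52% with quantile normalization, 49.7% with normexp and quantile, 56.9% with median centring and 55% with the deposited table. The median difference over all genes was -0.17 as scaled here and 0.15, 0.07, 0.22 and 0.19 under those 4 scalings. Differences are given relative to the 75th percentile.

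Keratinocyte differentiation genes were higher in keratinocytes for 23 of 26 tested members and in hepatocytes for none, with a median of 8.46 (camera adjusted p = 1.24e-10, and adjusted p = 0.0555 with an estimated correlation and 0.0606 with the deposited table). Involucrin (IVL), a scaffold of the cornified envelope, was at least 1590-fold higher (log2 10.64 ± 0.11), and keratin 1 (KRT1), a keratin of suprabasal layers, at least 155-fold. Transglutaminase 1 (TGM1), which cross-links the envelope, was 17-fold higher. Keratin 10 (KRT10) lay at similar levels in both types (log2 0.42, adjusted p = 0.00185), below the fold threshold, but at 1.33 with signals mapped on the spike-ins. Outside the lists, the largest measured differences toward keratinocytes were KLK11, a serine protease (1420-fold, log2 10.48 ± 0.53), TNS4, a focal adhesion protein (1150-fold), keratin 13 (KRT13, 1090-fold) and the envelope protein SPRR2D (957-fold).

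Basal keratinocyte genes were higher in keratinocytes for 13 of 15 and in hepatocytes for 2, the integrin ITGA3 and the linker DST, which ended as calls under median centring (median 7.75, camera adjusted p = 8.79e-06, and adjusted p = 0.0555 with an estimated correlation). Keratins 5 and 14 (KRT5, KRT14), the keratin pair of the basal layer, were saturated in keratinocytes and at least 2520-fold and at least 2120-fold higher. TP63, the master regulator of stratified epithelia, was at least 399-fold higher (log2 9.99 ± 0.69, adjusted p = 9.15e-05) and the hemidesmosome integrin ITGB4 33.6-fold. Genes of epithelial junctions were higher in keratinocytes for 20 of 22 and in hepatocytes for none (median 3.84, camera adjusted p = 8.05e-08, and adjusted p = 0.0555 with an estimated correlation). Desmoplakin (DSP) was saturated in keratinocytes and at least 6.74-fold higher, EPCAM 18.3-fold and ESRP1 25.4-fold. CDH1 was not called (log2 3.85 ± 1.70, adjusted p = 0.0944), but its adjusted p was 0.00954 without either IMR90 array.

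Interferon response genes were higher in keratinocytes for 12 of 18 and in hepatocytes for 1, BST2, a membrane tether of viruses (median 1.41, camera adjusted p = 4.64e-04, and adjusted p = 0.0783 with an estimated correlation and 0.0849 with the deposited table). The antiviral genes IFIT1, OAS1 and MX1 were 6.72-fold, 6.42-fold and 4.21-fold higher. ISG15, a ubiquitin-like modifier, had a log2 difference of 0.56 and was not called, but 1.32 and called with signals mapped on the spike-ins.

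All 24 tested plasma protein genes were higher in hepatocytes, with a median of -10.40 (camera adjusted p = 1.85e-10, and adjusted p = 0.0783 with an estimated correlation). Albumin (ALB), the main protein of plasma, was saturated in hepatocytes and at least 9030-fold higher there, and the protease inhibitor SERPINA1 at least 293-fold. APOA1, the main apolipoprotein of high-density lipoprotein, was at least 1200-fold higher (log2 -10.23 ± 0.08, adjusted p = 1.76e-07) and the fibrinogen chain FGB at least 3820-fold. Further genes with the largest measured differences toward hepatocytes were the plasma protein ITIH3 (4000-fold), the membrane protein TM4SF4 (2660-fold), the secreted liver protein FGL1 (2450-fold) and AEBP1, a matrix protein (5200-fold, log2 -12.34 ± 0.10).

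Of the genes of drug and bile acid metabolism, 19 of 21 were higher in hepatocytes and none in keratinocytes (median -6.45, camera adjusted p = 1.05e-05, and adjusted p = 0.0555 with an estimated correlation). CYP3A4, which oxidises many drugs, was 24-fold higher, the bile acid transporter SLC10A1 10.9-fold and CYP2E1 4.56-fold. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was not called (log2 -0.54, adjusted p = 0.381). Enzymes of the urea cycle, amino acids and glucose were higher in hepatocytes for 15 of 18 (median -3.86, camera adjusted p = 1.23e-04, and adjusted p = 0.0758 with an estimated correlation and 0.749 with the deposited table). Arginase (ARG1) was 42.8-fold higher, ornithine transcarbamylase (OTC) at least 10.0-fold and PCK1, an enzyme of glucose synthesis, 3.76-fold. CPS1, the entry enzyme of the urea cycle, had a log2 difference of 0.24 and was not called.

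Liver transcription factors were higher in hepatocytes for 11 of 15 (median -3.68, camera adjusted p = 0.00513, and adjusted p = 0.0783 with an estimated correlation and 0.353 with the deposited table), a direction that turned with the filter on all 8 arrays (adjusted p = 0.782). FOXA2, a pioneer factor of endoderm, was 11-fold higher. FOXA1 (log2 -0.64, adjusted p = 0.279) and CEBPA (log2 -0.35, adjusted p = 0.454; saturated in keratinocytes) were not called, though CEBPA was at -2.40 and called with the mean of its probes. HNF4A, a nuclear receptor central to hepatocytes and chosen after its values were seen, did not pass the background filter on the probe used.

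Genes of other cell types were also higher in hepatocytes than in keratinocytes. Fibroblast matrix genes were higher for 23 of 25 (median -5.66, camera adjusted p = 4.64e-08, and adjusted p = 0.0555 with an estimated correlation). COL1A1 was saturated in hepatocytes and at least 219-fold higher, COL3A1 446-fold, COL1A2 132-fold and FN1 24.1-fold. Contractile and mesenchymal genes were higher for 13 of 18 and lower for 2, S100A4 and CAV1 (median -3.59, camera adjusted p = 0.0202, and adjusted p = 0.111 with an estimated correlation). TAGLN, ACTA2 and VIM were at least 72.3-fold, at least 62.7-fold and at least 16.2-fold higher in hepatocytes, while TWIST1 was not called (log2 -0.40).

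Macrophage and leukocyte genes were higher in hepatocytes for 14 of 19 and in keratinocytes for none, with a median of -3.84 (camera adjusted p = 3.3e-04, and adjusted p = 0.0555 with an estimated correlation and 0.0685 with the deposited table). Median centring called 1 of 19 as higher in keratinocytes. The scavenger receptor CD163 of macrophages was 40.4-fold higher in hepatocytes, the lipopolysaccharide receptor CD14 16.5-fold and the leukocyte antigen PTPRC at least 3.34-fold. CD68 was not called (log2 -0.18). Endothelial genes were higher in hepatocytes for 11 of 14 and in keratinocytes for none (median -2.48, camera adjusted p = 0.00463, and adjusted p = 0.134 with an estimated correlation). The endothelial adhesion molecule PECAM1 was at least 30.9-fold higher and CDH5, the cadherin of endothelial junctions, 2.97-fold. VWF was not called (log2 -0.64). KDR, counted among the 11, was dim in both types on the probe used and gives no fold.

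Genes of mitosis and DNA replication were higher in hepatocytes for 22 of 26 and in keratinocytes for none (median -2.43, camera adjusted p = 1.12e-04, and adjusted p = 0.0555 with an estimated correlation). TOP2A, which untangles DNA before division, was 23.4-fold higher, the mitotic kinase CDK1 24-fold, MKI67 at least 5.58-fold and cyclin B1 (CCNB1) 3.13-fold.

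The HOX clusters differed in direction. HOXA genes were higher in keratinocytes for 7 of 10 and in hepatocytes for 1, HOXA3, which was saturated in both types (median 3.02, or 1.69 with dim sides at their bound; camera adjusted p = 0.0143, and adjusted p = 0.254 with an estimated correlation and 0.667 with the deposited table). HOXA7 and HOXA9 were at least 387-fold and at least 314-fold higher in keratinocytes. HOXA5 was 11.5-fold higher and HOXA6 at least 2.81-fold. HOXA10 was at least 9.54-fold higher on the chromosome 12 probe, but at -0.02 with the deposited table. The probe was chosen anew for that table and was another one. The chromosome 12 probe, at -3.24 in keratinocytes and -8.37 in hepatocytes, would not give -0.02. HOXA11, counted among the 7, was not above background in hepatocytes, and its level of -6.7 in keratinocytes was too low to give a fold. HOXA2 (log2 0.10) and HOXA4 (log2 0.04) were not called. HOXC genes were higher in keratinocytes for 6 of 7 (median 4.59, camera adjusted p = 2.99e-04, and adjusted p = 0.0859 with an estimated correlation), among them HOXC9 by at least 135-fold, HOXC10 by at least 21-fold, HOXC8 by at least 8.85-fold and HOXC6 by at least 1.43-fold. HOXD genes were higher in keratinocytes for 4 of 6 (median 1.57, camera adjusted p = 0.039, or 0.0705 with normexp and quantile, 0.0774 with quantile, 0.103 with median centring, 0.173 with no filter on dim probes and 0.078 with signals mapped on the spike-ins, and adjusted p = 0.134 with an estimated correlation), namely HOXD1 by at least 10.5-fold, HOXD8 by at least 7.97-fold, HOXD9 by 3.74-fold and HOXD3 by at least 1.1-fold, a call that ended without any single array but hepatocyte replicate 1 (log2 between 0.60 and 1.30). The HOXD3 call also ended with the replicate block (log2 1.24, limma adjusted p = 0.0502) and with signals mapped on the spike-ins (1.02, adjusted p = 0.0802). The list's adjusted p was 0.0528 without IMR90 replicate 1 and 0.0506 without IMR90 replicate 2. HOXB genes were higher in hepatocytes for 5 of 9 and in keratinocytes for none (median -2.04, camera adjusted p = 0.0657, or 0.0481 without hepatocyte replicate 2, 0.0422 with the pairs averaged, 0.0325 with median centring, 0.0477 with normexp and quantile, 0.0497 with signals mapped on the spike-ins and 0.0222 with outlier spots kept), with HOXB3 49.3-fold, HOXB4 37.2-fold, HOXB2 36.0-fold and HOXB5 6.11-fold higher. HOXB5 was not called without hepatocyte replicate 1 (adjusted p = 0.0568) or replicate 2 (0.0597).

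**Figure D5:**
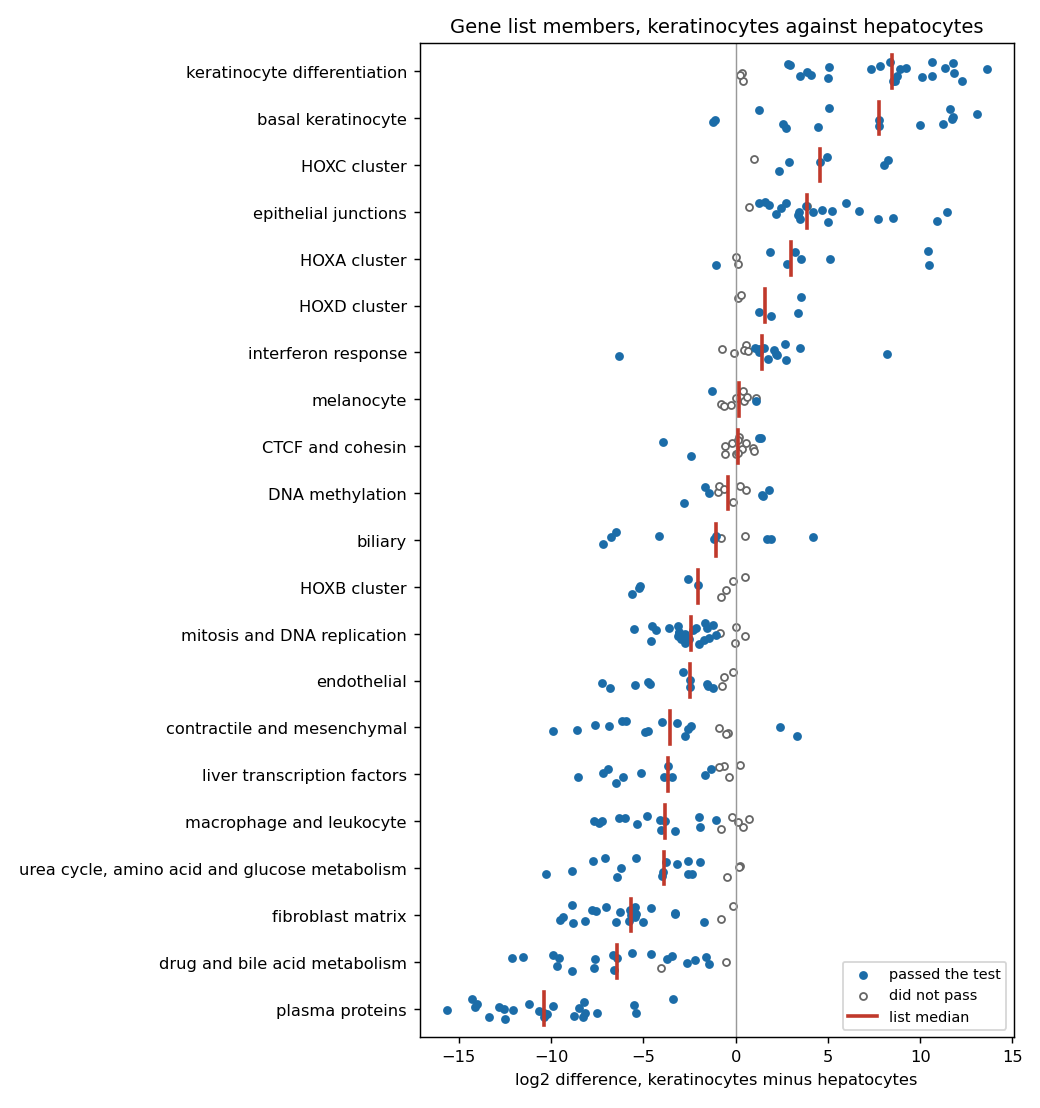
Log2 difference keratinocytes minus hepatocytes of each tested member of the gene lists on the horizontal axis, a row per list, with the list's median marked. Keratinocyte differentiation members had a median of 8.46 and plasma protein members a median of -10.40.

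Of 27 lists, 18 passed camera in keratinocytes minus hepatocytes, 4 with the filter on all 8 arrays and 0 with an estimated correlation. With normexp and quantile, the calls that ended included those of HOXA6, HOXA11, HOXC6, HOXD3, MKI67, MLANA, OTC, PCK1, PTPRC and CDH5. Among 6231 genes with several measured probes, 64 had probes that differed in opposite directions (1.03%).

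The 4 comparisons between slides cannot separate the cell types from the slides. H1 minus keratinocytes gave 15447 called genes, 6695 higher in H1 and 8752 higher in keratinocytes, and the median over all genes was -0.28. The share higher in H1 was 43.3%, and 47.1% with median centring (median -0.13) and 51.8% with the filter on all 8 arrays. With outlier spots kept it was 48.4% (median -0.07). Pluripotency genes were higher in H1 for 15 of 17 and in keratinocytes for 1 (median 9.64, camera adjusted p = 0.0073, and adjusted p = 0.41 with an estimated correlation and 0.576 with the deposited table), a direction that turned with the filter on all 8 arrays (adjusted p = 0.893). SOX2 was at least 1950-fold higher in H1, NANOG 799-fold on 1 usable H1 array and DNMT3B at least 336-fold. POU5F1 was at least 58.7-fold higher but not called (adjusted p = 0.0624). It was called, at log2 5.88, without IMR90 replicate 1 and equally without replicate 2. Leaving out either array takes the spread between the IMR90 arrays out of the fit. Keratinocyte differentiation genes were higher in keratinocytes for 22 of 26 (median -8.45, camera adjusted p = 3.66e-04, and adjusted p = 0.21 with an estimated correlation, 0.235 with the deposited table and 0.894 with the filter on all 8 arrays), among them IVL by at least 2220-fold, TGM1 by at least 491-fold and KRT1 by at least 190-fold. KRT10 was saturated in H1 and not called (log2 0.69), and turned to -2.74 with signals mapped on the spike-ins. HOXA genes were higher in keratinocytes for 9 of 10 (median -4.37, or -2.62 with dim sides at their bound; camera adjusted p = 0.0298, and adjusted p = 0.391 with an estimated correlation and 0.576 with the deposited table), with HOXA7 at least 464-fold and HOXA9 at least 373-fold higher.

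H1 minus hepatocytes gave 15657 called genes, 6034 higher in H1 and 9623 higher in hepatocytes. The share higher in H1 was 38.5%, and 51% with median centring and 49.3% with the deposited table. The median over all genes was -0.52 as scaled here, against 0.02 and -0.04. Plasma protein genes were higher in hepatocytes for all 24 tested (median -10.84, camera adjusted p = 3.75e-07, and adjusted p = 0.153 with an estimated correlation and 0.163 with the filter on all 8 arrays), with SERPINA1 at least 7650-fold, ALB at least 7380-fold, FGB at least 2660-fold and APOA1 at least 904-fold higher. Pluripotency genes were higher in H1 for 15 of 17 and in hepatocytes for 1 (median 8.40, camera adjusted p = 0.0017, and adjusted p = 0.341 with an estimated correlation and 0.593 with the deposited table; direction turned with the filter on all 8 arrays, adjusted p = 0.923), among them SOX2 by at least 2210-fold, NANOG by 221-fold on 1 usable H1 array and DNMT3B by at least 48.3-fold. POU5F1 was not called (adjusted p = 0.0617), but was called, at log2 5.88, without IMR90 replicate 1 and equally without replicate 2. Macrophage and leukocyte genes were higher in hepatocytes for 15 of 17 (median -6.17, camera adjusted p = 0.0017, and adjusted p = 0.126 with an estimated correlation, 0.0684 with the deposited table and 0.405 with the filter on all 8 arrays), including CD68 by at least 138-fold, CD14 by 115-fold, CD163 by at least 55.9-fold and PTPRC by at least 2.33-fold. HOXA genes were higher in hepatocytes for 3 of 10 and in H1 for 1, HOXA9, dim in both (median -0.41, or 0 with dim sides at their bound; camera adjusted p = 0.512). HOXA4, HOXA5 and HOXA2 were at least 27.4-fold, at least 2.61-fold and at least 2.22-fold higher in hepatocytes. With normexp and quantile the calls of HOXA5 (log2 -0.33), HOXA2 (-0.52), HOXA9 (0.33) and PTPRC (-0.29) ended, and 3 of 4 tested HOXA genes were higher in H1 and 0 in hepatocytes with the deposited table.

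IMR90 minus keratinocytes gave 14493 called genes, 5795 higher in IMR90 and 8698 higher in keratinocytes, with a median over all genes of -0.36. The share higher in IMR90 was 40%, and 49.2% with median centring (median -0.02) and 52.4% with the filter on all 8 arrays. Fibroblast matrix genes were higher in IMR90 for all 23 tested (median 6.54, camera adjusted p = 7.78e-11). This was the only list past the threshold of any comparison with an estimated correlation (adjusted p = 0.0436 with an estimated correlation). COL3A1 was at least 522-fold higher on 1 usable IMR90 array, COL1A1 at least 125-fold, COL1A2 at least 92.4-fold and FN1 at least 14.2-fold. Keratinocyte differentiation genes were higher in keratinocytes for 22 of 25 (median -10.43, camera adjusted p = 4.5e-05, and adjusted p = 0.0972 with an estimated correlation, 0.218 with the deposited table and 0.953 with the filter on all 8 arrays), with IVL at least 1920-fold, TGM1 at least 439-fold and KRT1 at least 164-fold higher. KRT10, saturated in IMR90, was not called (log2 0.51) and turned to -2.77 with signals mapped on the spike-ins. HOXA genes went both ways, with 3 of 9 higher in IMR90 and 5 in keratinocytes. Their median was -1.56 and their mean -0.87, while camera ranked the list toward IMR90 (adjusted p = 0.695). HOXA2, HOXA5 and HOXA4 were 9.60-fold, 5.54-fold and 3.46-fold higher in IMR90, and HOXA9 was 100.0-fold higher in keratinocytes.

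IMR90 minus hepatocytes gave 13965 called genes, 4571 higher in IMR90 and 9394 higher in hepatocytes. The share higher in IMR90 was 32.7%, and 43.6% with quantile normalization, 42.7% with normexp and quantile, 53.9% with median centring and 51.3% with the deposited table. The median over all genes was -0.55, against -0.16, -0.07, 0.17 and 0.04. All 24 plasma protein genes were higher in hepatocytes (median -11.67, camera adjusted p = 1.61e-07, and adjusted p = 0.135 with an estimated correlation and 0.172 with the filter on all 8 arrays), with ALB at least 6380-fold, SERPINA1 at least 3190-fold, FGB at least 2300-fold and APOA1 at least 782-fold higher. Fibroblast matrix genes were higher in IMR90 for 11 of 23 and in hepatocytes for 2 (median 0.95, camera adjusted p = 8.88e-04, and adjusted p = 0.131 with an estimated correlation), a direction that turned with signals mapped on the spike-ins, where 9 were higher in IMR90 and 12 in hepatocytes. The list's adjusted p was 0.0918 with quantile normalization, 0.387 with the deposited table, 0.0875 with the filter on all 8 arrays and 0.652 with that mapping. COL1A1, COL1A2 and FN1 were saturated in IMR90 and not called, and COL3A1 had a log2 difference of 0.23. With signals mapped on the spike-ins all 4 were called as higher in hepatocytes, at -3.97, -3.56, -3.90 and -2.23. HOXA genes were higher in IMR90 for 5 of 9 and in hepatocytes for none, or for 4 of 9 without the HOXA10 call on the chromosome 12 probe (median 1.83, or 0.67 with dim sides at their bound, camera adjusted p = 0.00489, and adjusted p = 0.275 with an estimated correlation and 0.937 with the deposited table). HOXA5 was 63.7-fold, HOXA2 10.3-fold, HOXA4 3.55-fold and HOXA9 at least 3.14-fold higher. HOXA10 was at -1.96 (limma adjusted p = 0.00214) with the deposited table, where its probe was chosen anew and was not the chromosome 12 probe. It was at 0.14 and not called with the mean of its probes and at 0.73 with normexp and quantile.

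Genes highest in a type passed the test against each of the other 3. They numbered 2548 in H1, 1143 in IMR90, 1876 in keratinocytes and 2572 in hepatocytes. In H1 the clearest were TNFRSF8, with a smallest log2 difference of 9.29, CA14, a carbonic anhydrase (8.78), and SEMA6A, a guidance protein (8.13), the last 2 on 1 usable H1 array. In IMR90 they were LRRC17 (7.92), the small GTPase DIRAS3 (5.37) and WNT5A, a signalling protein of mesenchyme (5.35). In keratinocytes they were TNS4 (9.21), LRATD1 (8.24) and TMEM40 (7.67). In hepatocytes they were the plasma protein AHSG (7.98), ASGR2, a subunit of the asialoglycoprotein receptor (7.66), and SGCA, a sarcoglycan of muscle (7.48). Median centring gave 1718 in IMR90 and 1670 in hepatocytes, and the number in hepatocytes was 1578 with normexp and quantile and 1491 with the deposited table. Leaving out flagged spots removed mostly bright spots of slide 1. In brightness decile 9, 40.88% of spots were flagged as non-uniform on H1 replicate 1 and 0.3459% on keratinocyte replicate 1. With outlier spots kept the numbers were 3200 in H1, 1615 in IMR90, 1812 in keratinocytes and 2505 in hepatocytes.

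HOX genes above background differed by type and cluster. Of 11 HOXA genes, 1 was above background in H1, 6 in IMR90, 10 in keratinocytes and 4 in hepatocytes. Of 10 HOXB genes the numbers were 1, 7, 8 and 8, of 9 HOXC genes 0, 2, 7 and 0, and of 9 HOXD genes 1, 0, 6 and 1, in the same order. The genes above background in H1 were HOXA3, HOXB7 and HOXD9, and in hepatocytes those of the HOXA cluster were HOXA2, HOXA3, HOXA4 and HOXA5. A gene counted if any of its probes was above background on both arrays. HOXA3 counted in H1 only through its brighter probe, its other probe being above background on neither H1 array. The lowest level well above background was -7.229 and -7.337 on the keratinocyte arrays and between -6.26 and -6.832 on the others. HOXA11, at -6.7 in keratinocytes, lay near the limit of those other arrays.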

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

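All tests in this part were chosen after the results were seen, and no biological explanation was tested for these patterns. RNA of other cells is weighed below as a property of the samples.

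A signal in control spots, which no comparison used, differed between the slides. Over the 5 E1A spike-ins, control RNAs added to the samples, the log2 signal on slide 1 had a slope of 1.37 per log2 on slide 2. The slide 1 minus slide 2 differences ran from -1.39 and -1.67 for the dimmest spike-ins to 1.61 for the brightest, a range of 3.28, which argues against a different amount of the same mix on the slides, since that would move all 5 alike. A steeper response of slide 1 stays open. The spike-in spans were alike in the cell types of a slide, 10.58 to 11.34 log2 over H1 and IMR90 and 7.99 to 8.08 over keratinocytes and hepatocytes. For the probe signals, such a response cannot be told apart from the cell types that each slide holds. The quantiles of the probe signals at the spike-in levels had a slope of 1.32, but the slide difference of 10693 genes measured on all 8 arrays stayed between -0.26 and -0.38 over 5 bins of brightness.

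Genes of H1 were brighter on IMR90 replicate 1 than on replicate 2. Over 15 genes bright in H1 and dim in keratinocytes and hepatocytes, chosen without the IMR90 values, the median difference was 1.95 (quartiles 0.95 and 2.57), against -0.17 for 620 keratinocyte genes and -0.13 for 517 hepatocyte genes. Noise like that of the keratinocyte and hepatocyte genes is argued against, since the highest median among 10000 random sets of 15 of them was 1.11. The random sets were not matched in brightness to the H1 genes. The H1 genes had to be bright in H1, the others only above background in their type. On IMR90 replicate 1, 8 of the 15 H1 genes were above background, against 74 of 620 keratinocyte and 140 of 517 hepatocyte genes. On IMR90 replicate 2 the counts were 4, 56 and 137 of the same sets. A small amount of H1 RNA or signal on IMR90 replicate 1 may account for it, and where it would have entered was not tested. POU5F1, not called at 5.93 with both arrays, passed the test without either of them, at 9.76 without replicate 1 and 2.11 without replicate 2.

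Genes of fibroblasts, leukocytes and endothelium were above background on the hepatocyte arrays. Of the leukocyte and endothelial members tested, 63.6% were higher there than in each other type (13 of 19 and 8 of 14), as RNA of other liver cells in the samples would give, and this stays a candidate explanation. The share was lower for bile duct genes (27.3%, 3 of 11), and for the fibroblast matrix (8%, 2 of 25) and contractile (5.56%, 1 of 18) lists, where IMR90 fibroblasts are among the types compared. IMR90 RNA on these arrays is argued against, since 74 of 227 IMR90 genes (32.6%) lay over 4 log2 lower there than in IMR90, and the leukocyte list lay a median of 5.16 higher there than in IMR90. The fibroblast matrix median of keratinocytes minus hepatocytes stayed at or below -5.27 under all 5 scalings. Those scalings moved the median over all genes only between -0.17 and 0.22. Shifts of that size are too small to make this difference, so the outcome was fixed beforehand. Mapping signals on the spike-ins was not among the 5. The share of leukocyte and endothelial members was not recomputed under other scalings, so an effect of scaling on that share stays open. For the most abundant members, ALB and COL1A1 were both saturated on the hepatocyte arrays, so no share of other cells can be read from these levels, and expression of these genes by the hepatocytes themselves stays open and untested.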

How the results depend on the processing

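The alternatives with outlier spots kept, signals mapped on the spike-ins, averaged keratinocyte and hepatocyte arrays, the crossed replicate block, and calls with both sides dim or saturated left out were chosen after seeing the data. Of 285 values of named genes in a comparison, 206 kept their direction and side of the threshold under every alternative that gave them a value. Under the filter on all 8 arrays many named genes had no value. Single genes past the test under neither setting changed sign in 60 instances, over 32 genes and comparisons, and these changes were counted as kept. Unless the construction is named, the cause was not tested.

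With normexp and quantile the called genes numbered 6710 in H1 minus IMR90, 9949 in H1 minus keratinocytes, 10138 in H1 minus hepatocytes, 8422 in IMR90 minus keratinocytes and 7821 in IMR90 minus hepatocytes. Genes highest in hepatocytes then numbered 1578, and HOX calls over the 6 comparisons 73 in place of 124. The filter on all 8 arrays, which tests fewer genes, gave 5843 in H1 minus IMR90, 5985 in keratinocytes minus hepatocytes, 8903 in H1 minus keratinocytes, 8871 in H1 minus hepatocytes, 8027 in IMR90 minus keratinocytes and 7580 in IMR90 minus hepatocytes, with 1405 genes highest in H1, 828 in keratinocytes and 982 in hepatocytes, and 1 HOX call. The adjusted p alone, which drops the fold threshold, gave 16367 in H1 minus IMR90 and 18133 in keratinocytes minus hepatocytes, with 4739, 2209, 3716 and 4896 genes highest in H1, IMR90, keratinocytes and hepatocytes. An absolute log2 difference of at least 2, a stricter threshold, gave 5780, 4923, 9324, 9837, 7976 and 8050 in H1 minus IMR90, keratinocytes minus hepatocytes, H1 minus keratinocytes, H1 minus hepatocytes, IMR90 minus keratinocytes and IMR90 minus hepatocytes, with 1301, 502, 832 and 1221 genes highest in the 4 types. Median centring gave 1718 genes highest in IMR90 and 1670 in hepatocytes. The deposited table gave 1491 highest in hepatocytes and 79 HOX calls.

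Gene lists past the threshold in H1 minus IMR90, keratinocytes minus hepatocytes, H1 minus keratinocytes, H1 minus hepatocytes, IMR90 minus keratinocytes and IMR90 minus hepatocytes numbered 5, 9, 4, 6, 7 and 3 with the deposited table, which lacks values for many dim spots and so tests fewer members. They numbered 1, 4, 1, 6, 5 and 1 with the filter on all 8 arrays, and 0, 0, 0, 0, 1 and 0 with an estimated correlation. Under the filter on all 8 arrays, which leaves few members, 3 lists changed sign: liver transcription factors in keratinocytes minus hepatocytes (adjusted p = 0.782), pluripotency in H1 minus hepatocytes (0.923) and pluripotency in H1 minus keratinocytes (0.893).

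Some genes reversed. HOXA3 in H1 minus keratinocytes was -1.03 with quantile normalization, -2.95 with the mean of its probes and -3.47 with signals mapped on the spike-ins, which also gave -3.35 in IMR90 minus keratinocytes, and the mean of its probes gave 1.11 in IMR90 minus hepatocytes. HOXA10 with the deposited table was -1.96 in IMR90 minus hepatocytes and -0.02 in keratinocytes minus hepatocytes, on a probe chosen anew rather than the chromosome 12 probe of the main calls. SUZ12 with the mean of its probes was 2.08 in H1 minus IMR90. With signals mapped on the spike-ins, COL3A1 was -2.23 in IMR90 minus hepatocytes, and KRT10 was -2.74 in H1 minus keratinocytes and -2.77 in IMR90 minus keratinocytes.

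Leaving out each array in turn, with the lone array assumed to vary like the other groups, called genes ranged from 9946 to 10260 in H1 minus IMR90, 9809 to 10437 in keratinocytes minus hepatocytes, 14625 to 15556 in H1 minus keratinocytes, 14727 to 15733 in H1 minus hepatocytes, 13685 to 14661 in IMR90 minus keratinocytes and 13131 to 14114 in IMR90 minus hepatocytes. Genes highest in a type ranged from 2186 to 2517 in H1, 946 to 1134 in IMR90, 1759 to 1873 in keratinocytes and 2393 to 2559 in hepatocytes. Lists past the threshold ranged from 8 to 11, 16 to 19, 9 to 11, 12 to 13, 10 to 12 and 12 to 15 in the order above, and HOX calls from 116 to 125.

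The numbers do not pair arrays across types, since the correlation across genes of same-number deviations ran from -0.114 to 0.0881. With the replicate block the called genes numbered 10257 in H1 minus IMR90, 10283 in keratinocytes minus hepatocytes, 15404 in H1 minus keratinocytes, 15598 in H1 minus hepatocytes, 14464 in IMR90 minus keratinocytes and 13906 in IMR90 minus hepatocytes. With a crossed replicate block, in which the numbers of the IMR90 arrays were exchanged, they were 10258, 10293, 15403, 15611, 14441 and 13896.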

Other observations

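Among genes of DNA methylation, DNMT3A, DNMT3B and DNMT3L were higher in H1 than in IMR90, by at least 28.3-fold, at least 102-fold and at least 2.76-fold, and the oxidase TET2 and the methyl-DNA readers MBD1 and MBD2, chosen after their values were seen, were higher in IMR90. With 3 of 12 on each side the list's median was -0.01, its mean 0.03 and its camera adjusted p 0.975. Median centring gave 3 higher in H1 and 5 in IMR90, and leaving out IMR90 replicate 1 gave 3 and 1 of 8. In keratinocytes minus hepatocytes DNMT1, the maintenance methyltransferase, was 3.23-fold higher in hepatocytes, DNMT3A 2.71-fold and DNMT3B 6.94-fold (log2 -2.80, but not called with outlier spots kept, adjusted p = 0.124, or with the arrays of each type averaged, adjusted p = 0.133), while TET2, MBD1 and MBD2 were higher in keratinocytes (median -0.39, camera adjusted p = 0.534). DNMT1 had a log2 difference of 0.43 in H1 minus IMR90 and was not called.

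CTCF, the insulator protein that shapes chromatin loops with cohesin, was 2.58-fold higher in H1 than in IMR90 (log2 1.37 ± 0.11, limma adjusted p = 1.7e-04) and 2.63-fold higher in keratinocytes than in hepatocytes. In H1 minus IMR90 the list had 3 of 12 members higher in H1 and 1, the cohesin subunit STAG1, 2.61-fold higher in IMR90 (median 0.40, camera adjusted p = 0.56). The cohesin genes RAD21 (log2 0.24) and SMC1A (log2 0.54) were not called. In keratinocytes minus hepatocytes 2 of 15 members were higher on each side (median 0.11, mean -0.12, camera adjusted p = 0.148), and RAD21 (log2 0.19), SMC1A (log2 -0.56) and SMC3 (log2 0.04) were not called. In H1 minus IMR90 CTCF was at 1.00 and below the fold threshold with normexp and quantile. Quantile normalization, median centring and the deposited table each gave 4 higher in keratinocytes and 2 in hepatocytes.

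Genes of early lineages were higher in H1 than in IMR90 for 4 of 11, FOXA2, CER1, NES and OTX2, and lower for 1, CDX2, with these 5 chosen after their values were seen and FOXA2 not above background in either type (median 0.87, camera adjusted p = 0.56). SOX17 (log2 -0.67, or -1.39 and called without H1 replicate 1), TBXT (log2 -0.70, or -1.17 and called without IMR90 replicate 1) and GSC (log2 1.49, or 3.29 and called without IMR90 replicate 2) were not called, and MIXL1 was not above background in either type. Bile duct genes in keratinocytes minus hepatocytes went both ways. KRT7 was 3.22-fold and SOX9 18.3-fold higher in keratinocytes, with KRT7 below the fold threshold with the deposited table (log2 0.96). SPP1, a secreted phosphoprotein, was 89.0-fold higher in hepatocytes, while KRT19 was saturated in both. In all 3 of 11 were higher in keratinocytes and 6 in hepatocytes, with the saturated KRT19 counted among the 6 (median -1.05, camera adjusted p = 0.416), or 3 and 2 of 10 with the deposited table. Of 10 melanocyte genes, MLANA was 2.17-fold higher in keratinocytes, but below the fold threshold with normexp and quantile (log2 0.58) and with signals mapped on the spike-ins (0.85). OCA2, chosen after its values were seen, was higher in hepatocytes. PMEL (log2 0.46), TYR (log2 1.12) and TYRP1 (log2 -0.78) were not called (median 0.18, camera adjusted p = 0.83), and quantile normalization called 3 as higher in keratinocytes and 0 in hepatocytes.

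Of 18 housekeeping genes, B2M and SDHA were called in H1 minus IMR90, both higher in IMR90 (median 0.18, mean -0.03, camera adjusted p = 0.304), and 2 were higher in keratinocytes and 5 in hepatocytes in the other comparison within a slide, 4 of the 5 saturated on both sides and 6 in hepatocytes when adjusted over the list alone (median -0.63, camera adjusted p = 0.364). The first 3 principal components of 10693 genes measured on all 8 arrays held 47.9%, 29.6% and 21.5% of the variance, and the first separated the slides.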
